A study of Mus musculus with 16 samples.

How the data were processed

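Liver total RNA from 16 mice was hybridised to 1-colour Agilent mouse arrays, 1 array per sample. Per the labels, the mice were male ApoE knockouts with a stated age of 8 weeks, livers were taken after 8 weeks, and Cy3-labelled cRNA was made from 0.5 µg of RNA. The 8 ctrl-inh and 8 miR-185-inh mice were assigned from the treatment field of the labels and keep the mouse numbers of their titles. Slide and array position were read from the deposited scanner files: slide 1 with scan 1 holds all ctrl-inh arrays and slide 2 with scan 2 all miR-185-inh arrays, so slide could not be fitted as a block.

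The deposited scanner files hold, per spot, an intensity that Feature Extraction 11.5.1.1 had background-subtracted and detrended, per the file headers, together with the median intensity of the spot and of its local background. The submitters' processing notes name Agilent Feature Extraction 9.1 instead. The authors' value table is on a log2 scale: each of its columns equalled log2 of the processed intensity of its array minus 1 constant, with an SD of the difference of at most 0.0069. The genes were not centred and the direction needs no setting, while how the constant was chosen is not given in the sources used here. Its column medians ran from -1.30 to -1.22.

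Values were taken as log2 of the processed intensity minus each array's 75th percentile over non-control spots. Spots marked as outliers were left out and spots of 1 probe averaged. Probes were kept when well above background on at least 8 of the 16 arrays, counted without regard to group, and a gene was represented by its brightest probe. The scanner files as used here give accessions, which were matched without version to the RefSeq table of assembly GRCm38 for names only, because the array grid is on build mm9. Of 55681 probes 26762 were named, giving 20284 symbols, and 715 of the 716 listed symbols were matched. Features without a match kept the file's identifier.

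Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Single genes were also tested with an exact permutation test over all 6435 splits of the 16 mice into 8 and 8. Gene lists, 24 of processes and 10 of cell types, were tested with camera at a preset correlation of 0.01, adjusted over all 34, with camera at an estimated correlation and fry as alternatives. Intervals of list medians are 95% bootstrap intervals over mice (2000 draws). Correlations across mice were tested over all 40320 pairings within a group. On simulated data with the spread of these arrays and 25626 genes, limma recovered 73% of 100 genes changed 1.5-fold and 90% of 100 changed 2-fold, with 9 false calls, and camera called the 1 shifted list. The noise was drawn independently for each gene. The simulation therefore cannot show how often camera calls a list falsely when its genes vary together.

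Groups, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule names Cyp7a1, Foxo1, Apoe, Srebf2, Scarb1 and others not reported here, then the 10 largest rises and 10 largest falls among called genes with a regular symbol, then up to 4 members with the smallest p of the 3 bile acid lists and of each list past camera. Alternatives fixed at the same time were normexp (offset 50) in place of the scanner's correction, quantile normalization, a percentile over probes detected on all arrays, the authors' table, other filters on dim probes, the mean of a gene's probes, other eBayes and array weight settings, slide row and column as covariates, and a replicate block over shared mouse numbers. Normexp had been planned on the mean spot signal and was run on the median spot signal, the column read here. A test of miR-185 seed sites in 3' UTRs was planned and is not analysed here, since no UTR annotation was used.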

Results

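Liver gene expression was measured in 16 male ApoE knockout mice on a high-fat diet, 8 given a control inhibitor (ctrl-inh) and 8 given a lentiviral antisense inhibitor of the microRNA miR-185 (miR-185-inh). ApoE knockout mice lack apolipoprotein E and accumulate cholesterol-rich lipoproteins. The title and design of the series place the question at bile acid metabolism, with Cyp7a1 and the transcription factor FoxO1 as its named players. Each array carried 59305 non-control spots, and between 58.7% and 74.8% of them were well above background. The median signal per array ran from 182 to 268, and any 2 arrays correlated across genes with r between 0.984 and 0.996. After filtering, 25786 features were tested, 15245 of them with a RefSeq gene name. All ctrl-inh arrays lay on one slide and all miR-185-inh arrays on another, each slide with its own scan, so slide, scan and treatment cannot be told apart in any comparison given here. The labels number the samples, each taken here as 1 mouse, without stating that they came from separate animals, so p-values measure the spread between these samples, which may be technical. Each slide held its arrays in 2 rows of 4, and within the ctrl-inh slide the rows differed in 1199 features by limma. The number of arrays limits the precision.

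Cyp7a1, the rate-limiting enzyme of the classical bile acid pathway, averaged 1.44 ± 0.54 (SD, n = 8) in ctrl-inh livers and 2.15 ± 0.62 (SD, n = 8) in miR-185-inh livers, in log2 units relative to each array's 75th percentile. The difference was 0.71 (SE 0.27), a 1.64-fold higher level, and 7 of the 8 miR-185-inh mice lay above the ctrl-inh mean. Foxo1, which encodes a transcription factor restrained by insulin signalling, averaged 1.74 ± 0.09 (SD, n = 8) and 2.02 ± 0.26 (SD, n = 8), a difference of 0.29 (SE 0.10) or 1.22-fold, also with 7 of 8 mice above the ctrl-inh mean. Neither gene passed the adjustment over all features in limma, with adjusted p = 0.136 for Cyp7a1 and 0.0970 for Foxo1. Taken singly, the two-sided exact permutation test of the group means gave p = 0.0247 for Cyp7a1 and 0.00404 for Foxo1. On the Foxo1 probe used, miR-185-inh mice 3 and 6 had the highest values, 2.29 and 2.53, against 1.72 to 1.999 in the other miR-185-inh mice. This pattern was seen only after the values were examined. The Foxo1 difference was 0.25 without mouse 3 and 0.22 without mouse 6, so its size rests partly on them. Leaving out both together was not run. A dimmer Foxo1 probe differed by 0.22 (exact permutation p = 0.179). The Cyp7a1 difference was 1.34 among the arrays of row 1 (limma adjusted p = 0.135) and 0.079 among those of row 2 (adjusted p = 0.851). The limma test of the difference between the rows gave an adjusted p of 0.206 over all features. Before adjustment this row test was slightly stronger than the limma test of the Cyp7a1 group difference. A dependence of the Cyp7a1 difference on slide row is thus neither shown nor excluded, and rows were examined after the main results were seen.

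**Figure D1:**
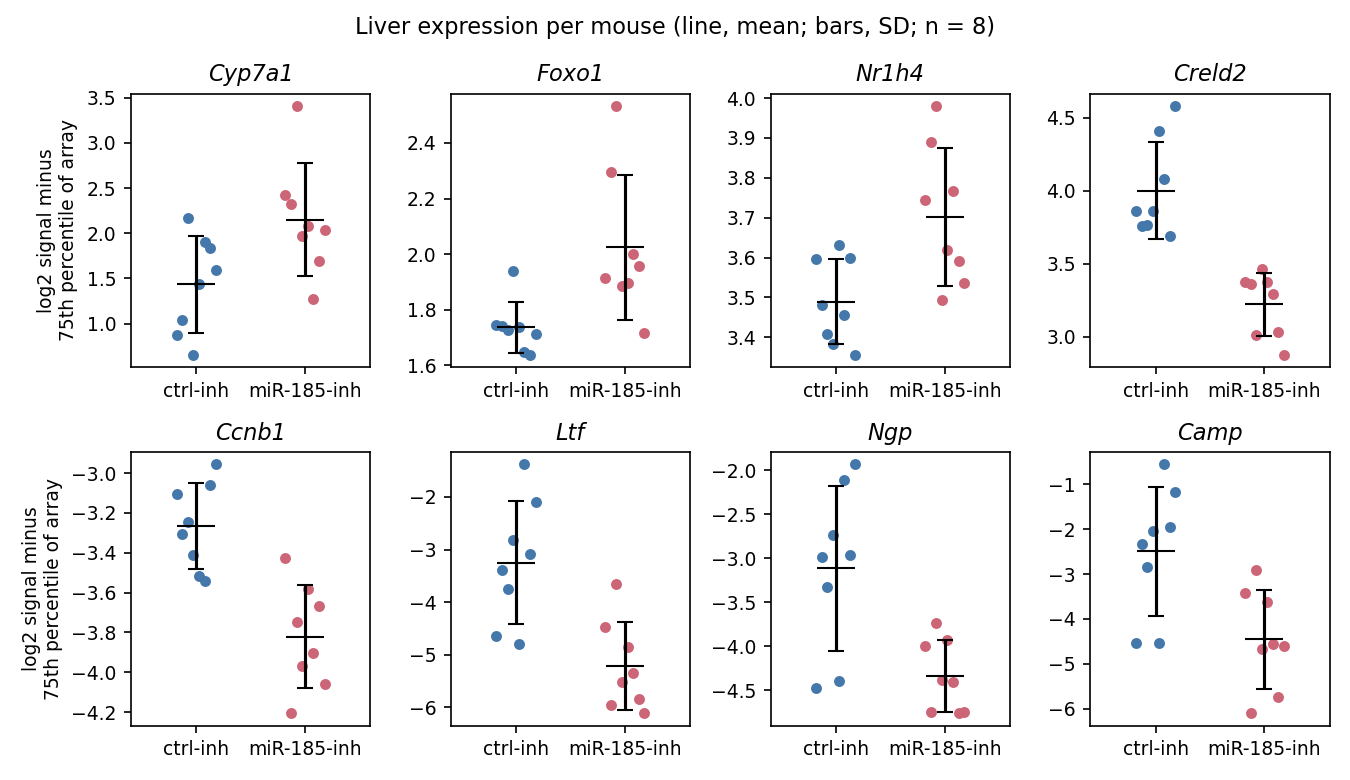
Log2 signal minus the 75th percentile of each array for 8 genes in liver, 1 point per mouse, with the group mean as a line and the SD as bars (n = 8 per group). Cyp7a1 averaged 1.44 in ctrl-inh and 2.15 in miR-185-inh livers with overlapping mice, while all 8 miR-185-inh values of Ltf, Ngp, Ccnb1 and Creld2 lay below the ctrl-inh mean.

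Apoe, Srebf2 and Scarb1, also fixed for reporting, did not pass the adjustment over all features. Apoe, the knocked-out gene, gave a bright signal of 3.87 ± 0.35 (SD, n = 8) in ctrl-inh and 4.15 ± 0.27 (SD, n = 8) in miR-185-inh livers; whether its probe lies outside the deleted part is not known here, so it checks nothing about genotype. Its difference of 0.28 had an exact permutation p of 0.100. Srebf2 (-0.022) and Scarb1 (0.013), which encode the master regulator of sterol synthesis and the HDL receptor, differed by less than the SD between mice, with exact permutation p of 0.900 and 0.813. A dimmer probe of each, well above background on all 16 arrays, differed by -0.31 for Srebf2 (exact permutation p = 0.210) and 0.14 for Scarb1 (exact permutation p = 0.667).

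Across all features, 1214 differed between the groups at an adjusted p under 0.05 in limma, 320 higher and 894 lower in miR-185-inh livers, so that 26.4% of the calls were higher. Of the RefSeq-named genes 631 were called, 231 higher and 400 lower. A change of at least 1.5-fold was reached by 337 features, 36 higher and 301 lower. The largest rises among named genes were in Gpcpd1, a glycerophosphocholine phosphodiesterase (log2 difference 1.19, SE 0.27, adjusted p = 0.0197), in Ccny, which encodes cyclin Y (1.16, adjusted p = 0.0229), and in Dkk4, a secreted Wnt antagonist (1.13, adjusted p = 0.0412). Klhl13 (0.97), Tenm3 (0.92), F2rl2 (0.89), Cbx8 (0.86), Tsc22d2 (0.84), Rad54l2 (0.75) and Adam6b (0.74) completed the 10 largest rises. F2rl2 was well above background on 4 ctrl-inh and 7 miR-185-inh arrays, Adam6b on 5 and 8, and the other rises on all 16. MiR-185-inh mice 1 and 3 had the 2 lowest values of their group for Ccny, Klhl13, Tenm3, Cbx8, Tsc22d2 and Rad54l2, a pattern seen only after their values were examined. Ccny was -1.85 and -1.42 in them, within the ctrl-inh range, and -0.31 to 0.021 in the other miR-185-inh mice, and Klhl13 was -1.33 and -1.69 against -0.61 to -0.31. Cbx8, a Polycomb protein, and Tsc22d2 each had an exact permutation p of 0.000155, the smallest the 6435 splits can give.

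Of the 10 largest falls among named genes, Rad51b and Ngp were well above background on all 16 arrays. Rad51b, a DNA repair gene, fell by 1.26 on the log2 scale (SE 0.26, adjusted p = 0.0131), and Ngp, the neutrophilic granule protein, fell by 1.22 (adjusted p = 0.0429). Ltf, which encodes lactotransferrin of neutrophil granules, fell by 1.97 (SE 0.46, adjusted p = 0.0241) and was well above background on all 8 ctrl-inh arrays and on 3 of the 8 miR-185-inh arrays. Mrgpra2a fell by 1.61, Spag16 by 1.44, Tcl1b5 by 1.22 and Spink4 by 1.15, each well above background on 7 ctrl-inh arrays and 1 miR-185-inh array. Olfr464 fell by 1.33 (6 and 2 arrays well above background), Olfr1181 by 1.29 (7 and 2) and Cstdc4 by 1.21 (7 and 4). The sizes of these 8 falls, and so their order, rest partly on signals not well above background. Other probes of Spag16 and Tcl1b5 differed by 0.80 and -0.62, well above background on 1 and 4 arrays. After normexp the calls of Ngp, Cstdc4, Olfr464, Spink4 and Dkk4 ended, and after quantile normalization those of the first 4 of these and of Mrgpra2a, without a change of sign. Among the arrays of slide row 1 alone limma called 0 features, with 4608 at an unadjusted p under 0.05, and in row 2 alone 466. The split of calls depended on the scaling, with 396 higher and 457 lower after quantile normalization and 320 higher and 1529 lower when the percentile was taken over probes detected on all arrays. It was 549 higher and 602 lower after normexp, which here differs in both the background correction and the spot signal it starts from.

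**Figure D2:**
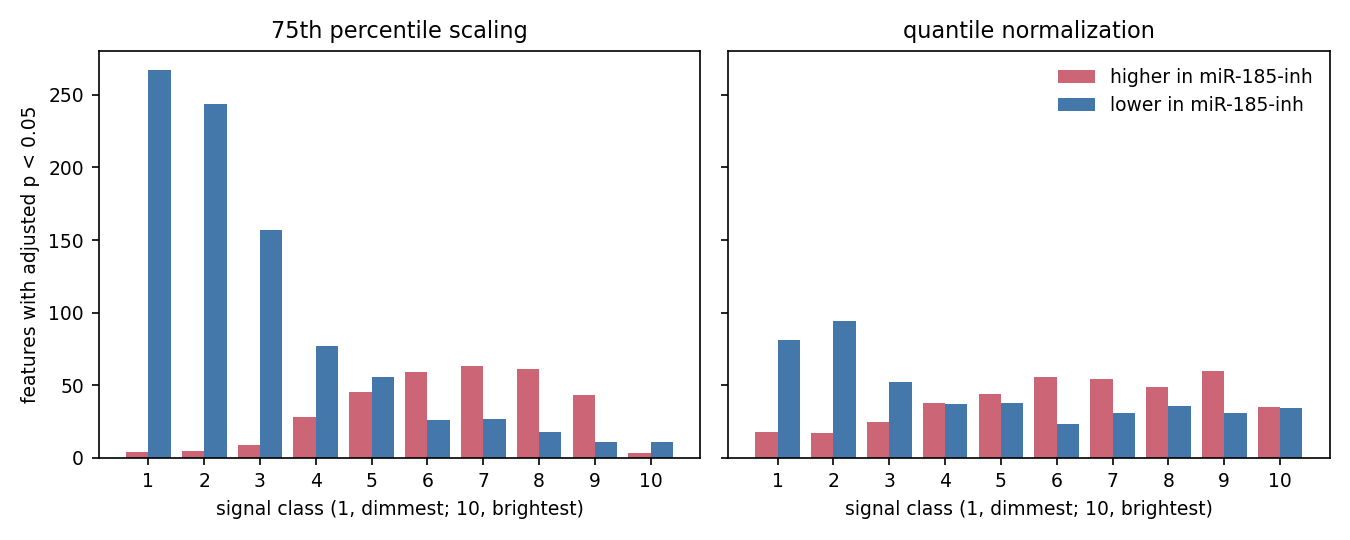
Number of features with a limma adjusted p under 0.05 in 10 classes of equal size by mean signal, from class 1 (dimmest) to class 10 (brightest), after 75th percentile scaling (left) and quantile normalization (right). Under 75th percentile scaling the 3 dimmest classes held 267, 244 and 157 lower calls, and under quantile normalization 81, 94 and 52.

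Genes of bile acid synthesis did not pass the test as a list. Of 19 members tested, 10 were above and 9 below zero, with a median log2 difference of 0.022 (camera adjusted p = 0.808), which turned to -0.0035 after normexp. It was 0.077 in slide row 1 and -0.053 in row 2, and the test of that difference gave an adjusted p of 0.00619, or adjusted p = 0.587 with an estimated correlation. Cyp46a1, a cholesterol hydroxylase, was the 1 member that passed over all genes and also the 1 that passed adjusted over the list alone; it fell by 0.41 (SE 0.11, adjusted p = 0.0373) at a dim signal, well above background on 7 ctrl-inh and 3 miR-185-inh arrays, and its call ended after normexp and after quantile normalization. Besides Cyp46a1 and Cyp7a1, the members with the smallest p were Scp2, a peroxisomal sterol carrier (-0.20, adjusted p = 0.121), and Akr1c6 (-0.15, adjusted p = 0.225). The list of bile acid and canalicular lipid transporters had a median of -0.027 over 15 members (adjusted p = 0.933), and none passed over all genes or adjusted over the list alone. Its members with the smallest p were Atp8b1 (-0.25), Slc10a1 (-0.28), the bile acid uptake transporter, Abcg8 (0.31) and Abcg5 (0.14), the last pair being sterol exporters. Abcg8 was -0.59 and -0.51 in miR-185-inh mice 3 and 6. It was -1.43 to -1.21 in the other miR-185-inh mice, against a ctrl-inh mean of -1.43, a pattern seen only after the values were examined. Slc10a1 had values in 6 ctrl-inh mice, since its spot was marked as an outlier in mice 9 and 11, and a dimmer probe of it differed by -0.049 (exact permutation p = 0.694).

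The list of bile acid regulators rose, with a median of 0.12 over 21 members, 16 of them above zero (camera adjusted p = 0.0395, or adjusted p = 0.988 with an estimated correlation), although no single member passed over all genes or adjusted over the list alone. Foxo1 (0.29), Mafg (0.19), Nr2f2 (0.31) and Nr1h4 (0.21), the bile acid receptor FXR, had the smallest p. Nr0b2, the FXR-induced repressor SHP, differed by -0.41. The call also ended after normexp (median 0.11, adjusted p = 0.0811), quantile normalization (0.093, adjusted p = 0.0665), averaging of probes (0.064, adjusted p = 0.200), and slide row and column as covariates (adjusted p = 0.0533). It also ended without miR-185-inh mouse 3 (median 0.072, adjusted p = 0.107) or mouse 6 (0.083, adjusted p = 0.0511), and the median was 0.18 in slide row 1 and 0.028 in row 2. Mafg was measured by 3 probes, of which the one used differed by 0.19 and the others by -0.13 and -0.080.

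Neutrophil markers fell most clearly of the 34 lists. All 12 members tested were below zero, the median was -0.82 (camera adjusted p = 3.45e-05), 2 members passed over all genes, and 8 passed adjusted over the list alone. The call ended with an estimated correlation (adjusted p = 0.988) and with fry (adjusted p = 0.107). Before adjustment camera with an estimated correlation gave p = 0.0538 and fry p = 0.00316. With an estimated correlation 0.988 was the lowest adjusted p of the 34 lists, so that value does not rank them. Ltf and Ngp were the 2, followed by Camp, the antimicrobial peptide cathelicidin (-1.96, adjusted p = 0.0626), and Mpo, myeloperoxidase (-1.51, adjusted p = 0.0666). Camp was well above background on 8 ctrl-inh and 6 miR-185-inh arrays, and Mpo on 7 and 3. Ctrl-inh mice 1 and 8 had the 2 lowest ctrl-inh values of these 4 genes, within the miR-185-inh range, a pattern seen only after the values were examined. Camp was -4.53 and -4.54 in them against a miR-185-inh mean of -4.45, and Ltf -4.64 and -4.80 against -5.22. Over all genes Camp and Mpo passed without ctrl-inh mouse 1 (adjusted p = 0.0344 and 0.0412) or mouse 8 (0.0371 and 0.0367), and Camp after normexp, with a Camp log2 fold change of -1.51 (adjusted p = 0.0478). The median was -1.11 among the arrays of slide row 1 and -0.49 among those of row 2.

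Proliferation genes fell, with a median of -0.21 over 21 members and 17 of them below zero (camera adjusted p = 0.0412, or adjusted p = 0.988 with an estimated correlation). Ccnb1 (-0.55, adjusted p = 0.0130) and Plk1 (-0.53, adjusted p = 0.0291), a mitotic cyclin and a mitotic kinase, passed over all genes and adjusted over the list alone. Both calls over all genes ended after normexp (-0.32, adjusted p = 0.0676 for Ccnb1; -0.34, adjusted p = 0.0898 for Plk1), that of Plk1 after quantile normalization (-0.44, adjusted p = 0.0940) and that of Ccnb1 with averaged probes (-0.76, adjusted p = 0.0903). The call of Plk1 also ended without ctrl-inh mouse 2 or 3 or miR-185-inh mouse 6, 8, 9 or 10, with the Plk1 log2 fold change between -0.52 and -0.49 and adjusted p from 0.0504 to 0.0571. Other probes of Ccnb1 differed by -0.48 (exact permutation p = 0.143) and by -1.25, the last well above background on 8 arrays. Ccna2 had a value of -0.55, and Ccne1, the G1/S cyclin, went the other way with 0.70 (adjusted p = 0.129). Ccne1 was -0.58 and 0.033 in miR-185-inh mice 3 and 6. It was -2.08 to -1.68 in the other miR-185-inh mice, against a ctrl-inh mean of -2.17, a pattern seen only after the values were examined. The list of the unfolded protein response also fell (median -0.093, 17 of 20 below zero, adjusted p = 0.0492, or adjusted p = 0.988 with an estimated correlation). Creld2, an endoplasmic reticulum stress gene, fell by 0.78 (SE 0.13, adjusted p = 0.00463) and was the 1 member that passed over all genes. Adjusted over the list alone 4 members passed, namely Creld2, Sel1l (-0.51), Sdf2l1 (-0.40) and Hyou1 (-0.36). The call for proliferation also ended after normexp (median -0.19, adjusted p = 0.0704), quantile normalization (-0.13, adjusted p = 0.0711), the percentile over detected probes (-0.23, adjusted p = 0.114), no filter on dim probes (-0.19, adjusted p = 0.0606) and with slide row and column as covariates (-0.21, adjusted p = 0.0607). That for the unfolded protein response ended with the last 3 of these (medians -0.12, -0.093 and -0.093, adjusted p = 0.0508, 0.0606 and 0.0607) and with array weights (-0.086, adjusted p = 0.153). Leaving out single mice ended the proliferation call without ctrl-inh mice 1, 2, 3 or 4 (adjusted p = 0.101, 0.124, 0.128 and 0.0658) or miR-185-inh mice 1, 3 or 6 (0.0804, 0.107 and 0.0638), with medians from -0.24 to -0.19. It ended the unfolded protein response call without ctrl-inh mice 8, 9 or 12 (adjusted p = 0.103, 0.0552 and 0.0869) or miR-185-inh mice 1, 3, 6, 10 or 12 (0.0591, 0.107, 0.0511, 0.0661 and 0.133), with medians from -0.12 to -0.069. The proliferation median was -0.57 in slide row 1 and 0.019 in row 2, and the unfolded protein response median -0.0022 and -0.22, with adjusted p of 7.71e-06 and 0.00178 for the difference between the rows and adjusted p = 0.280 and 0.497 with an estimated correlation.

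**Figure D3:**
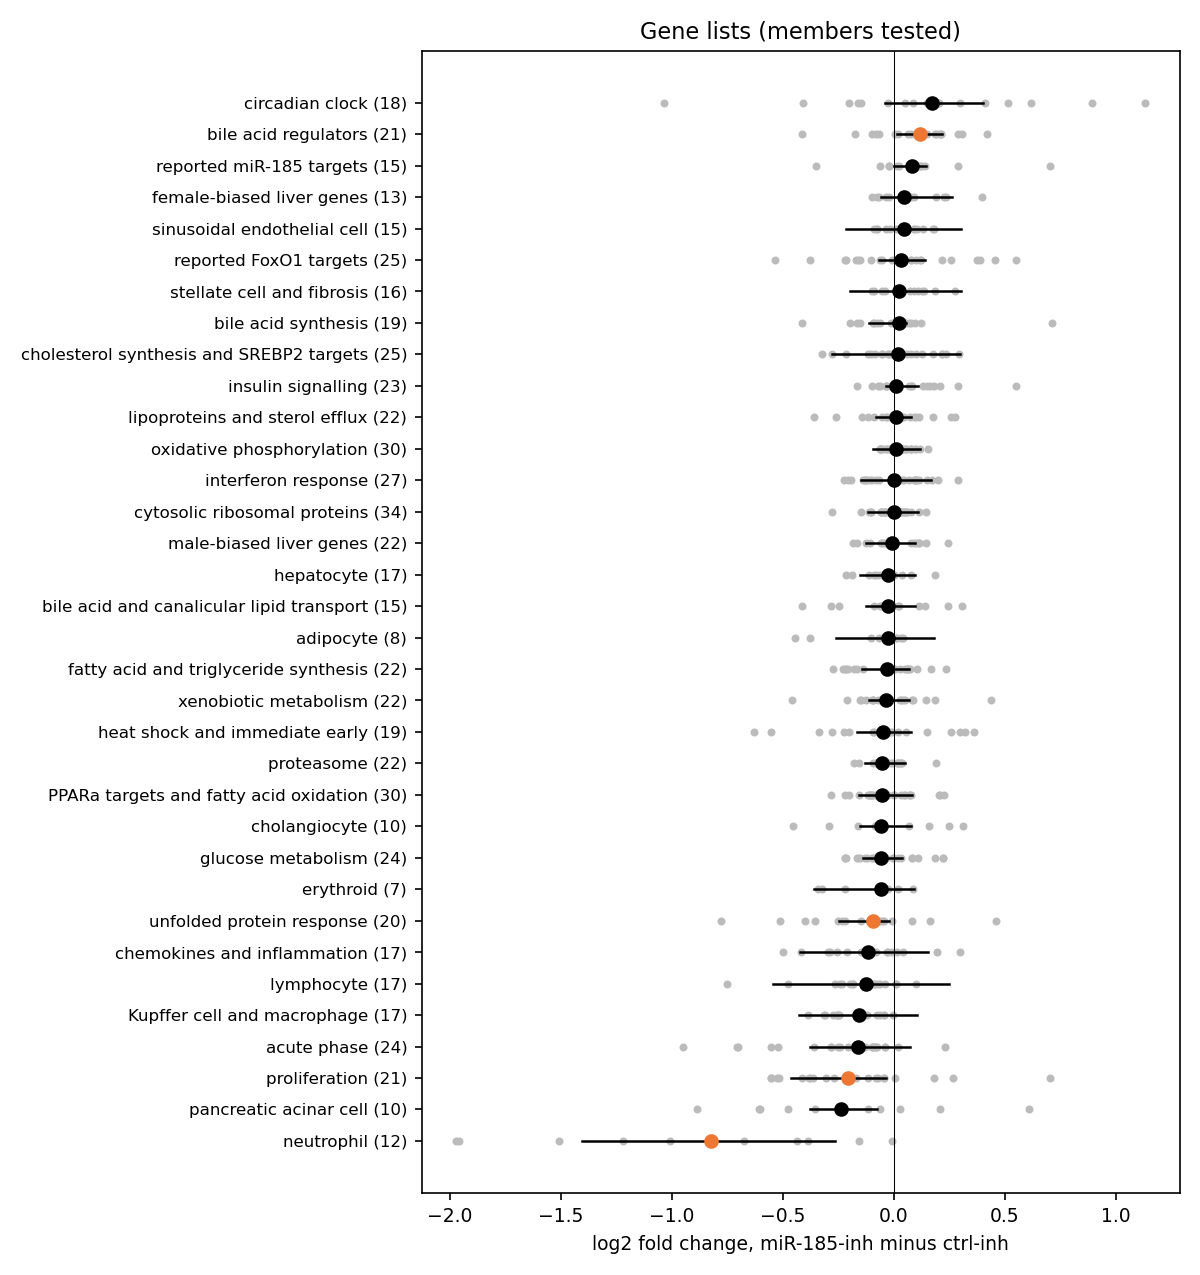
Log2 fold change of the members of the 34 gene lists (grey points), with the median of each list as a large point, orange where camera with preset correlation passed an adjusted p of 0.05, and a line for the 95% bootstrap interval of the median over mice. The neutrophil list has the lowest median, -0.82, and the circadian clock list the highest, 0.17, which did not pass. The clock list mixes genes of opposite phase, so its median cannot show a shift in phase.

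The other lists did not pass camera after adjustment. Acute phase genes had a median of -0.16 with 22 of 24 members below zero (adjusted p = 0.0654). The acute phase list shift passed with averaged probes (median -0.19, adjusted p = 0.0438), with the filter on all 16 arrays (adjusted p = 0.0272), in slide row 1 alone (-0.091, adjusted p = 0.0228), without ctrl-inh mouse 1, 2, 3 or 8 (adjusted p = 0.0469, 0.0320, 0.0499 and 0.0158) and without miR-185-inh mouse 9 (-0.22, adjusted p = 0.000128), and gave an adjusted p = 0.988 with an estimated correlation. Kupffer cell and macrophage markers had a median of -0.16 with all 17 below zero (adjusted p = 0.158). The Kupffer cell and macrophage median was -0.44 in slide row 1 and 0.17 in row 2, with an adjusted p of 2.27e-07 for the difference between the rows, or adjusted p = 0.376 with an estimated correlation. The circadian clock list had a median of 0.17 (adjusted p = 0.230), which was 0.29 in row 1 and -0.045 in row 2 (adjusted p = 0.227 for the difference). That list mixes genes of opposite phase, whose shifts cancel, so its test cannot decide whether clock phase differed. The pancreatic acinar list had a median of -0.24 (adjusted p = 0.230), and in it Cel, a bile salt-stimulated lipase, fell by 0.48 (adjusted p = 0.0171). Adjusted over the list alone 5 acinar genes passed, Cel, Cela3b (-0.36), Ctrb1 (-0.89) and Cela1 (-0.61) lower and Cela2a (0.61) higher. Reported miR-185 targets had a median of 0.081 over 15 members (adjusted p = 0.158), none of which passed over all genes. Adjusted over the list alone 1 of them passed, and it was lower in miR-185-inh livers. Reported FoxO1 targets had a median of 0.030 over 25 members (adjusted p = 0.371). Among heat shock and immediate early genes (median -0.050), the chaperone genes Hsph1 (-0.63) and Hsp90aa1 (-0.28) fell, and these and Hspb1 (-0.34) passed adjusted over the list alone. The genes of this paragraph were named after their values were seen. Medians were -0.12 for chemokines and inflammation, -0.13 for lymphocyte markers, -0.058 for erythroid markers, -0.057 for cholangiocyte markers, -0.057 for glucose metabolism, -0.053 for PPARa targets and fatty acid oxidation, -0.053 for the proteasome and -0.036 for xenobiotic metabolism. They were -0.030 for fatty acid and triglyceride synthesis, -0.029 for adipocyte markers, -0.025 for hepatocyte markers, -0.0097 for male-biased genes, -0.00079 for cytosolic ribosomal proteins and -0.00058 for the interferon response. They were 0.012 for insulin signalling, 0.011 for lipoproteins and sterol efflux, 0.011 for oxidative phosphorylation, 0.019 for cholesterol synthesis and SREBP2 targets, 0.025 for stellate cell and fibrosis markers, 0.043 for sinusoidal endothelial markers and 0.048 for female-biased genes. None of the members of the lists in these last 3 sentences passed over all genes or adjusted over the list alone. Median and camera direction differed in sign for bile acid synthesis, bile acid transport, male-biased genes, the interferon response and ribosomal proteins, and median and mean for bile acid synthesis (mean -0.0010) and male-biased genes (mean 0.0015).

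Within groups, Cyp7a1 was set against Foxo1, Nr0b2 and Hnf4a, making 6 relations over 8 mice each. In ctrl-inh livers Cyp7a1 and Foxo1 had r = -0.74 (exact permutation p = 0.0211, adjusted p = 0.126) and rho = -0.83 (exact permutation p = 0.0154, adjusted p = 0.0923). In miR-185-inh livers they had r = 0.68 (exact permutation p = 0.0751, adjusted p = 0.150) and rho = 0.31 (exact permutation p = 0.462, adjusted p = 0.693). Without the 2 mice farthest from the Foxo1 median, r was -0.56 in ctrl-inh and -0.50 in miR-185-inh livers (exact permutation p = 0.265 and 0.311), so the positive value rested on those mice. With Nr0b2, r was -0.67 in ctrl-inh (exact permutation p = 0.0614) and -0.45 in miR-185-inh livers (exact permutation p = 0.280), with rho of -0.62 in both (exact permutation p = 0.115). With Hnf4a, r was -0.13 and 0.43 and rho -0.21 and 0.14, with exact permutation p of 0.769 and 0.285 for r and 0.619 and 0.752 for rho. Without the 2 farthest mice, r was -0.17 and -0.64 with Nr0b2 and 0.12 and -0.47 with Hnf4a. No relation passed after adjustment. A slide row holds 4 mice of each group, so rows were not taken singly. With slide row removed and pairings permuted within rows, chosen after seeing the data, ctrl-inh livers gave r = -0.63 (exact permutation p = 0.253, adjusted p = 0.507) and rho = -0.86 (exact permutation p = 0.00868, adjusted p = 0.0260) with Foxo1. They gave r = -0.91 (exact permutation p = 0.0156, adjusted p = 0.0938) and rho = -0.81 (exact permutation p = 0.00868, adjusted p = 0.0260) with Nr0b2. These 2 relations thus passed by rho and not by r, and without the 2 farthest mice r was -0.49 and -0.60 (exact permutation p = 0.0278 and 0.250). With row removed, r was -0.65 with Hnf4a in ctrl-inh livers and 0.51, -0.31 and 0.41 with Foxo1, Nr0b2 and Hnf4a in miR-185-inh livers, and none of these 4 passed by r or rho.

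Spike-in RNA, which is added in equal amount to every sample, was lower on the slide of the miR-185-inh arrays, relative to the signal of each array's non-control spots. All 8 spike-in probes well above background on the 16 arrays were lower there, by 0.14 to 0.38 on the log2 scale, with a median difference of -0.24. The exact permutation p was under 0.05 for 6 of the 8, and the smallest was 0.0145. The median difference of all gene features was -0.03. Scaling each array to its non-control spots largely sets this gene median, so it cannot show whether genes shared the spike-in shift.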

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

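Of the tests in this part, those of the spike-in RNA, of higher, lower and 1.5-fold calls in other splits, of dim, brighter and higher calls under quantile normalization, and of the neutrophil list were chosen after the results were seen, and the sets of clock genes were picked after the clock values and Cyp7a1 had been seen.

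Among 94 groups of mice, 1 for each gene and treatment, examined for a single mouse far from the rest, 4 stood out, against 4.7 from chance at 1 in 20. Foxo1 in ctrl-inh mouse 4 was 1.94 against a median of 1.73 in the others, a gap of 0.639 of the group's range. Spink4 in ctrl-inh mouse 12 was -2.95 against -5.13, a gap of 0.748 of the range. Slc10a1 in miR-185-inh mouse 7 was 5.47 against 5.95, a gap of 0.583. Plk1 in ctrl-inh mouse 8 was -3.82 against -3.15, a gap of 0.632.

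The lower calls were concentrated in dim features, 668 of 894 in the 3 dimmest of 10 signal classes. Among 100 splits of the 16 arrays, the real split included, 1 gave as many changed genes (1214, highest other 681). As many changed 1.5-fold came in 1 (337, highest other 241). The lower and higher counts were each compared with the larger of the 2 directional counts of a split. That count reached the 894 lower calls in 1 split and the 320 higher calls in 2, with 489 the highest other. Chance is thus unlikely for these counts but is not excluded. Both groups fill the same positions on their slides, so the covariates of slide row and column, with which 89.2% of the called genes were still called, could not move the differences and say nothing about position. Quantile normalization left 34.0% of the dim lower calls, 70.4% of the brighter lower calls and 89.7% of the higher calls. A difference between the slides in the overall distribution of signal may thus underlie much of the first. As the whole cause of the others such a difference is argued against. Slide effects on single probes survive this normalization, so the values say nothing about them. The spike-in difference was 0.543 of the median size of the calls, between the bounds set for it, and any other slide effect cannot be told apart from the inhibitor.

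The neutrophil list lay at a median log2 difference of -0.82. A signal difference between the slides would shift equally dim genes alike, yet 10000 lists matched on signal had a 2.5th percentile of -0.17. Less blood in the livers would lower red cell genes too. The erythroid median of -0.058 over 7 genes had a 95% interval from -0.36 to 0.090. That lay narrowly above the bound of -0.41, set at 0.5 of the neutrophil median. The abundant Hba-a1, Hba-a2 and Hbb-b2 differed by -0.22, 0.086 and -0.026. The bound takes the neutrophil median as exact, while its own 95% interval ran from -1.40 to -0.27, so less blood is not excluded. Fewer neutrophils in the tissue, by treatment or by another difference between the sets of mice, stays open and was not tested.

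Cyp7a1 was higher in miR-185-inh livers by 0.71. A contrast of 8 clock output genes, Dbp and Per1 among them, with 5 of opposite phase, Arntl among them, differed between the groups by 0.92 (exact permutation p = 0.172), and lay between 1.53 and 2.98 in miR-185-inh mice 1, 3 and 6 and at most 0.44 in every other mouse of either group. By group mean all 8 output genes were higher and all 5 others lower in miR-185-inh livers, in sets picked after the clock values had been seen. MiR-185-inh mice 1, 3 and 6 all lay in slide row 1, so clock contrast and slide row partly coincide. Mice 1, 3 and 6 of that group also had its 3 highest Cyp7a1 values, 2.32 to 3.41, against 1.27 to 2.08 in its other mice. This was seen only after the values were examined. Mice 3 and 6 of that group also had the highest Foxo1 values, and clock phase was not tested for Foxo1. With the contrast as a covariate the Cyp7a1 difference was 0.49 (95% interval -0.11 to 1.09), an interval that holds both zero and the difference without it, so a part of clock phase is neither shown nor excluded with 16 mice. The slope of Cyp7a1 on the contrast was 0.24 (95% interval -0.00034 to 0.49). Harvest times are not used here, and the inhibitor stays open as an untested explanation.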

How the results depend on the processing

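Leaving out single mice, the separate slide rows, the 10 arrays without a block, the relations with slide row removed and the test of named features alone were chosen after seeing the data, as was the choice of lists followed singly here, made once many medians near zero were seen to change sign. Cyp7a1 and Foxo1 stayed higher and short of the threshold under every alternative run, Cyp7a1 between 0.079 and 1.34 (adjusted p 0.0806 to 0.851) and Foxo1 between 0.21 and 0.37 (adjusted p 0.0599 to 0.515). None of the relations of Cyp7a1 passed after normexp, quantile normalization or the percentile over detected probes or in the authors' table, and with slide row removed none passed by r and those with Foxo1 and Nr0b2 in ctrl-inh livers passed by rho (adjusted p = 0.0260). The neutrophil list stayed past camera's threshold except with an estimated correlation and with fry (adjusted p = 0.107). Dim signals limit the largest falls. The proliferation list also lost its call on the 10 arrays without a block (adjusted p = 0.0836). Ngp lost its call in 21 of 31 alternatives, Cyp46a1 in 19 of 30, Cstdc4 in 19 of 30, Olfr464 in 17 of 30, Dkk4 in 15 of 31, Plk1 in 12 of 31, Mrgpra2a in 10 of 30, Spink4 in 9 of 30, Ccnb1 in 6 of 31, and none of these changed sign. Calls were gained by Sel1l in 7 of 31, Sdf2l1 in 4 of 31, Camp in 3 of 30, Mpo in 2 of 30, Hyou1 and Ccna2 in 2 of 31, and Mafg, Nr1h4 and Scp2 in 1 of 31. The cause of the changes below was not tested, except that fewer arrays or features enter some settings.

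Features changed, higher, lower and changed 1.5-fold numbered 1214, 320, 894 and 337. Normexp gave 549 higher and 81 changed 1.5-fold, quantile normalization 457 lower and 150 changed 1.5-fold, the percentile over detected probes 1849 changed and 1529 lower, no dim filter 676 changed 1.5-fold, the filter on all 16 arrays 553 lower and 133 changed 1.5-fold, and array weights 579 higher. Named features alone gave 632 changed, 394 lower and 154 changed 1.5-fold. Slide row 1 alone gave 0 for all 4 counts, and row 2 alone 466 changed, 129 higher and 337 lower. Without single mice, changed ran from 735 to 1581, higher from 176 to 470 and lower from 546 to 1116. Changed was 794 and lower 564 without ctrl-inh mouse 11, 786 and 572 without ctrl-inh mouse 12, 766 and 590 without miR-185-inh mouse 6, and 735 and 546 without miR-185-inh mouse 7. Higher was 196 without ctrl-inh mouse 2, 213 without ctrl-inh mouse 3, 176 without miR-185-inh mouse 6 and 189 without miR-185-inh mouse 7.

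The replicate block over the 5 shared mouse numbers gave 0 changed, 0 higher, 0 lower and 0 changed 1.5-fold (2596 at an unadjusted p under 0.05), and the same 10 arrays without a block also 0 (2874). Deviations of same-numbered mice correlated between -0.13 and 0.11, so the numbers do not pair the samples. Of the 10 mice with shared numbers 1 correlated best with its own number. With the replicate block the bile acid synthesis median was -0.064 and Scarb1 -0.025, as without it on these arrays.

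Of 34 lists 4 passed; 2 did after normexp, quantile normalization, the percentile over detected probes or no dim filter, 1 with row and column covariates, 17 in row 1 alone, 7 in row 2 alone, 0 with an estimated correlation and 0 with fry. Without single mice 1 to 6 passed, 2 without miR-185-inh mouse 1 and 1 without mouse 3 or mouse 6. The bile acid synthesis median of 0.022 turned to -0.0035 after normexp, -0.0042 with the percentile over detected probes, -0.015 with averaged probes and -0.053 in row 2, and ran from -0.027 to 0.041 without single mice. Reported FoxO1 targets turned to -0.013 after normexp and -0.021 in row 2, and ran from -0.0094 to 0.073 without single mice. Transporters turned to 0.094 in row 1 and ran from -0.052 to 0.0035 without single mice. Sinusoidal endothelial markers turned to -0.016 with array weights and -0.32 in row 1, and ran from -0.038 to 0.095 without single mice. The acute phase list passed in 8 of 33 alternatives and reported miR-185 targets in 1 (row 1). Lymphocyte markers passed without a change of sign in 4 (row 1, without miR-185-inh mouse 10, the replicate block and the same arrays without it). In row 2 they passed with the opposite sign (camera adjusted p = 0.0405). Sinusoidal endothelial markers passed without a change of sign in 3 (row 2, the replicate block and the same arrays without it). In row 1 the endothelial markers passed with the opposite sign (camera adjusted p = 0.00116). In row 2 proliferation turned to 0.019 and lymphocyte markers to 0.38. The remaining 23 lists did not pass in the 13 settings that leave out neither single mice nor a row, and 10 of them changed sign there, the largest of their medians being 0.048 in size.

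Scarb1 turned to -0.013 with the percentile over detected probes and -0.055 in row 2, and Srebf2 to 0.042 with array weights and 0.20 in row 1. Slc10a1 turned to 0.17 with averaged probes, because 2 ctrl-inh mice without a value for the brighter probe were left with the dimmer one, and was -0.13 with each probe centred first, an alternative chosen after seeing the data. Mafg turned to -0.0081 with averaged probes and Apoe to -0.029 in row 2. Without single mice Scarb1 ran from -0.014 to 0.036 and Srebf2 from -0.11 to 0.050. Slide as a block could not be fitted, and the seed site test with its alternatives was not run.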

Other observations

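Slide row was examined after the main results were seen, and no explanation was tested. Row 1 holds the mice with the lower numbers of each group and row 2 those with the higher numbers, 4 of each group in a row. Interferon response genes had a median of -0.24 in row 1 and 0.26 in row 2, and chemokines and inflammation -0.60 and 0.23. Lymphocyte markers had -0.66 and 0.38, sinusoidal endothelial markers -0.32 and 0.33, and stellate cell and fibrosis markers -0.27 and 0.33. Kupffer cell and macrophage markers had -0.44 and 0.17, and cholesterol synthesis genes 0.19 and -0.12. By camera with preset correlation the shift differed between rows for 14 of the 34 lists, the interferon response with an adjusted p of 3.87e-11, and with an estimated correlation for none, the smallest adjusted p = 0.137. Neutrophil markers had -1.11 and -0.49, and their difference between rows had an adjusted p of 0.558. In single genes, the difference between the groups itself differed between rows for 96 features by limma.

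Among the 8 ctrl-inh arrays alone, the rows differed in 1199 features by limma, 568 higher and 631 lower in row 2. Among the 8 miR-185-inh arrays the rows differed in 0 features. Splitting all 16 arrays by row gave 394 features. On the ctrl-inh slide 68.6% to 74.8% of spots were well above background in row 1 and 58.7% to 64.2% in row 2. On the miR-185-inh slide the shares were 62.5% to 67.1% and 60.7% to 62.3%. The feature counts point to a structure among the ctrl-inh samples that follows row, mouse number and this share together. These cannot be told apart. In the arrays of row 1 alone, limma called 0 genes between the groups (4608 at an unadjusted p under 0.05), and in row 2 alone 466.

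Features of olfactory, vomeronasal and taste receptor families were examined after the dim lower calls were seen. Of 254 such features 45 were lower and 0 higher in limma, with a median of -0.25, and after quantile normalization 19 were lower and 0 higher, with a median of -0.11. Among all 25786 features 894 were lower and 320 higher, and among the 2579 of the dimmest signal class 267 and 4. The receptor features were not matched on signal. The filter of 8 of 16 arrays lets a dim feature pass mainly through ctrl-inh arrays, as Olfr464 (6 and 2) and Olfr1181 (7 and 2) did. A one-sided count may thus partly come from the filter, which was not tested.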
